A study of Mus musculus with 6 samples.

How the data were processed

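Total RNA from 6 mouse tumours was hybridised to Affymetrix gene expression arrays, 1 array per tumour. The tumours grew from glioma cells driven by a mutant epidermal growth factor receptor (EGFR), implanted under the skin of the flanks of immunodeficient Nu/Nu mice, per the labels' protocols. The labels divide them into 3 control gliomas, numbered 1, 2 and 4, and 3 gliomas that relapsed after the mutant receptor was switched off, numbered 1, 2 and 3. Per the labels' protocols, mice drank water with or without doxycycline at 2 g/L, tumours were collected at 2 cm3, and biotin-labelled cRNA was made from 5 ug of total RNA. The labels do not say which group received the drug, so neither is called treated here.

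The deposited table holds 1 log2 intensity per probe set and array, already normalized between arrays by the authors. The scale was read from the values, which ran from 1.93 to 14.2 with nearly equal quartiles. The medians were 6.60, 6.58 and 6.62 for control 1, 2 and 4 and 6.67, 6.68 and 6.67 for relapsed 1, 2 and 3. The submitters' processing notes name the affy package without a version. The methods of background correction, normalization and summarization are not given in the sources used here. Normalization between arrays sets their overall distributions alike, so a change shared by most transcripts could not be seen. Values were used as deposited, with no further normalization and no filter on dim probe sets.

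Probe sets were named from the platform annotation. Of 35556 probe sets, 21789 had 1 gene symbol, 1621 had several and 12146 were not listed with a gene. Genes were tested over the 19938 symbols of the first kind. For the 999 genes with more than 1 such probe set, the probe set with the highest mean over the 6 arrays stood for the gene. Older symbols in the gene lists were matched through the RefSeq gene table of assembly GRCm38.p6, from which no coordinates were taken.

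Differences were fitted with limma (version 3.58.1, R version 4.3.3), using lmFit and eBayes on the log2 values with relapsed against control as the only term. The fit had 4 residual degrees of freedom and a prior of 1.53. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all genes. A gene was called at an adjusted p under 0.05, and a second count also asked for a change of at least 2-fold. Errors given with the difference of a gene or probe set are standard errors (SE) from limma. Errors given with the difference of a list score or of the mean of Y-linked genes are SE without variance moderation. Errors given with a group's level are standard deviations (SD) over 3 arrays. The number of arrays limits the precision. The labels number the tumours separately but do not say whether they came from separate animals. The sample titles differ in number, and those of the controls alone end in R or L, which the labels do not explain. The p-values set differences against the spread between these samples, which need not be that between animals.

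Before the data were examined, 42 gene lists were fixed for pathways and cell types that such tumours could hold. Of their 639 entries, 593 were measured, and 41 lists with at least 5 measured genes were tested. They were tested with limma's camera, which asks whether the genes of a list moved further in one direction than the other genes, at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists. Each list was also tested with the correlation estimated from the data, with fry, which asks only whether the list's genes moved one way on balance, and with ranks. Per list, members were also counted with p-values adjusted over the list alone. List scores are the mean over the list's genes of the log2 value minus the gene's mean over the 6 arrays.

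The genes to be named were also set before the data were examined. They were the 12 largest rises and 12 largest falls among called genes whose groups did not overlap, leaving out unnamed clones and predicted genes, 11 fixed genes of receptor signalling and tumour suppression, and up to 4 called members of each list with the largest change. Where no member of a list was called, the 2 with the smallest p were taken. Of the fixed genes, 9 were measured by a probe set with 1 gene symbol, and the others were not analysed here. Other genes named in the text, among them further list members, were chosen after their values were seen.

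The spread within groups was the median over genes of the SD between the 3 arrays, and the mean absolute difference between pairs of arrays. It was compared by exact permutation of the 6 arrays into 2 groups of 3, which gives 10 splits and a smallest p of 0.1. Values were not centred on their group means first. The same splits were used to count how many genes and lists other groupings call.

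Alternatives set before the data were examined were leaving out the dimmer 50% of genes by mean signal, quantile normalization, median centring, the mean or median of a gene's probe sets, testing all probe sets, a variance prior with trend or a robust one, array weights, the replicate number as a block, a floor at the lowest 20% of values, a test without variance moderation, the other list tests, and leaving out each array in turn. The arrays with high marker levels of muscle, fat and keratinocytes were left out in 2 further fits, chosen after seeing the data.

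The procedure was tested on simulated data for the 19938 genes in 6 arrays, with 200 changed genes in each of 20 runs. It recovered 24.9% of genes changed by 0.5 on the log2 scale, 64.4% of those changed by 1, 87.7% of those changed by 2 and 96.0% of those changed by 3, with a mean of 6.85 false calls. The list test found a list of 20 genes shifted by 0.5 in 20 of 20 simulated runs, with a mean of 0.1 false calls among 40 unchanged lists. Simulated genes varied independently, which real genes do not. Figures were drawn with matplotlib (version 3.10.9).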

Results

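Gene expression was measured in 3 control gliomas and 3 gliomas that had relapsed after extinction of the mutant EGFR that drove them. The design asks how the transcriptome of tumours that regrew without the driving receptor differs from that of the control gliomas. Over genes, arrays of the same group correlated at r of 0.982 to 0.994 and arrays of different groups at 0.962 to 0.979. The first principal component held 58.0% of the variance and separated all 3 relapsed from all 3 control tumours.

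Relapsed tumours had lower levels of proneural and oligodendrocyte progenitor genes and higher levels of fibroblast and macrophage markers as lists in camera (adjusted p of 3.36e-04, 2.72e-06 and 2.49e-11). None of these lists passed when the correlation between genes was estimated, with adjusted p of 0.424, 0.507 and 0.424 with an estimated correlation. Olig2 and Olig1, transcription factors that specify oligodendrocyte progenitors, were lower. On the log2 scale Olig2 fell by 3.54 ± 0.43 (SE, 3 arrays per group), to 7.29 ± 0.70 from 10.84 ± 0.50 (SD), and Olig1 fell by 3.52 ± 0.36, to 7.87 ± 0.47 from 11.39 ± 0.55. Ogn, which encodes the small leucine-rich proteoglycan osteoglycin, rose by 4.21 ± 0.31, or 18.5-fold. Ccr2, the chemokine receptor of inflammatory monocytes, rose by 2.69 ± 0.41, or 6.47-fold. By limma with Benjamini-Hochberg adjustment, 1826 of 19938 genes changed, of which 735 rose and 1091 fell. At least 2-fold changes were found for 626 genes, 311 higher and 315 lower in relapsed tumours. With each array centred on its median instead, 696 genes rose and 1687 fell, so the balance of rises and falls depends on the scaling. With all 35556 probe sets tested, 871 probe sets rose and 860 fell, which is not a count of the same genes. It includes probe sets not listed with a gene, of which 189 rose and 114 fell. It also includes probe sets with several gene symbols, of which 75 rose and 7 fell. The groups did not overlap for 6131 genes, or 30.8%, against 10% by chance.

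Among the 12 largest rises were 4 small leucine-rich proteoglycans of connective tissue matrix. These were Ogn, Aspn (3.23 ± 0.34), Omd (2.78 ± 0.31) and Lum (2.76 ± 0.49), with adjusted p of 0.00713, 0.0130, 0.0139 and 0.0325 in limma. The control level of Omd, at 3.99, lay below 5.66, the median of probe sets not listed with a gene, so its fold is less certain than the others. The same holds for the control levels of Epha3 (5.57) and Fgf7 (5.59) and the relapsed levels of Usp51 (5.50) and Elavl4 (5.16), among called genes named by the fixed rule. Itgbl1, an integrin beta-like secreted protein, rose by 3.41 ± 0.22, or 10.6-fold. Crabp2, a cytoplasmic retinoic acid-binding protein, rose by 3.28 ± 0.40, and Glipr1 by 3.00 ± 0.26. Clec12a and Clec4a1, C-type lectin receptors of myeloid cells, rose by 2.78 ± 0.45 and 2.71 ± 0.48, and P2ry10b rose by 2.70 ± 0.21. Cldn1, a tight junction claudin, rose by 2.72 ± 0.35, or 6.57-fold.

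The largest fall was that of Htr3a, a subunit of the ionotropic serotonin receptor, which dropped by 4.24 ± 0.33, or 18.9-fold, with an adjusted p of 0.00810 in limma. Its relapsed level of 5.85 ± 0.63 (SD) lay close to the median of probe sets not listed with a gene. Sox8, a transcription factor of the oligodendrocyte lineage, fell by 2.78 ± 0.18, and Gjc3, a connexin of myelinating glia, fell by 2.82 ± 0.46. Trim9, a ubiquitin ligase enriched in brain, fell by 3.45 ± 0.32. Kcnip3, a calcium sensor that modulates potassium channels, fell by 3.13 ± 0.26, and Cacng5, an auxiliary subunit of calcium channels and glutamate receptors, fell by 3.01 ± 0.25. The remaining genes of this group were Fam181b, Aff2, Usp51 and Csdc2, which fell by 2.91, 2.91, 2.78 and 2.70.

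**Figure D1:**
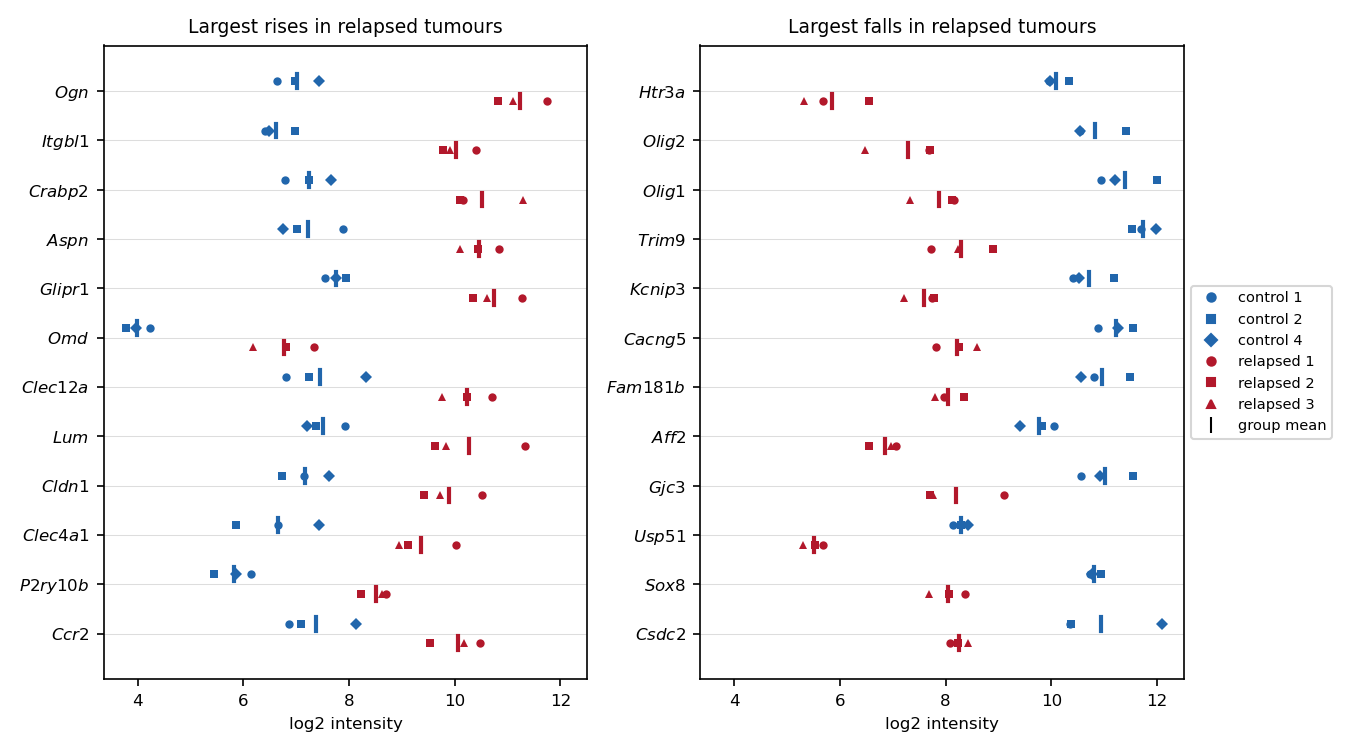
Log2 intensity (horizontal axis) of the 12 genes with the largest rises (left) and the 12 with the largest falls (right) in relapsed tumours, 1 point per array and a bar at each group's mean. The genes were chosen among those whose groups do not overlap, and Ogn has means of 11.23 in relapsed against 7.02 in control tumours.

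The gene counts depended on each single array. Without control 1, 2 or 4, limma called 415, 696 or 264 genes, and without relapsed 1, 2 or 3 it called 975, 424 or 297. Of 96 called genes named here by the fixed rule, 16 kept the call in all 6 of these fits, namely Ogn, Itgbl1, Glipr1, P2ry10b, Htr3a, Trim9, Kcnip3, Cacng5, Fam181b, Aff2, Usp51, Sox8, Dcn, Mrc1, S100a4 and Notch1. The call was lost in every one of them for 19, namely Birc3, Clec4a1, Csf1r, Ddit4, Eda2r, Etv1, Etv4, Fap, Fgf7, Foxm1, Hgf, Kif20a, Lrig1, Mx2, Ptprc, Robo4, Sox9, Tgfbr1 and Timp2.

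Egfr itself did not pass the test. Its level was 9.65 ± 0.38 (SD) in control and 9.89 ± 0.46 in relapsed tumours, a difference of 0.24 with a 95% interval of -0.50 to 0.98 and an adjusted p of 0.658 in limma. The probe set reads the mouse gene, and the labels do not say which form or species the mutant receptor had, so this value does not check its extinction. Met, the receptor of hepatocyte growth factor, was 1.16 ± 0.26 higher in relapsed tumours, with an adjusted p of 0.0542 in limma that ranged from 0.0243 to 0.530 over the alternatives. Erbb2, a receptor of the EGFR family, was 0.66 ± 0.15 lower, with an adjusted p of 0.0511 that ranged from 0.0304 to 0.425. Both narrowly missed the threshold although their groups did not overlap, and they passed it with the dimmer 50% of genes left out. The other fixed receptors did not pass in limma, with differences of 0.64 for Erbb3, 0.64 for Pdgfra, -0.57 for Igf1r, 0.20 for Fgfr1 and 0.16 for Axl and adjusted p of 0.216, 0.291, 0.123, 0.0933 and 0.534. Erbb3 passed without relapsed 2, with an adjusted p of 0.0429. Cdkn2a, the locus of the p16 and p19 cell cycle inhibitors, was 0.80 ± 0.41 lower with an adjusted p of 0.293, and by 0.32 without relapsed 1. The difference of Egfr was 0.041 without control 1, 0.42 without control 2, 0.022 without relapsed 1 and 0.48 without relapsed 2. That of Pdgfra was 0.32 without relapsed 3, that of Erbb3 0.42 without relapsed 1, and that of Axl 0.032 without control 2 and 0.078 without relapsed 3.

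Among 13 measured EGFR family receptors and ligands, 1 gene fell and none rose, or 2 fell when adjusted over the list alone. The gene that fell was Lrig1, a negative regulator of these receptors, at -0.85 ± 0.16. The list as a whole did not pass in camera, with an adjusted p of 0.870. Among 28 other receptor tyrosine kinases, 2 rose and 2 fell, or 6 and 5 when adjusted over the list alone, and the list gave an adjusted p of 0.923 in camera. Epha3, an ephrin receptor, rose by 1.46 ± 0.18, and Csf1r, the receptor of macrophage colony-stimulating factor, rose by 1.10 ± 0.23. Ntrk3, the neurotrophin-3 receptor, fell by 1.56 ± 0.16, and Ddr1, a collagen receptor, fell by 1.11 ± 0.18.

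Ligands of these receptors were higher as a list in relapsed tumours, with an adjusted p of 0.0196 in camera and an adjusted p of 0.424 with an estimated correlation. Of 24 measured ligands, 4 rose and none fell, or 5 rose when adjusted over the list alone. The scores of fibroblast and macrophage markers were higher in the same tumours, by 1.18 ± 0.27 and 1.24 ± 0.22. Hgf, the ligand of Met, rose by 2.61 ± 0.51, or 6.09-fold. Pdgfc, a platelet-derived growth factor, rose by 1.81 ± 0.17, Fgf7, a fibroblast growth factor of mesenchymal cells, by 1.68 ± 0.34, and Vegfc, a lymphatic endothelial growth factor, by 0.62 ± 0.10. The list did not pass with the dimmer 50% of genes left out (adjusted p = 0.135) or with all probe sets tested (adjusted p = 0.0581), in a range of 0.00661 to 0.424 over its alternatives.

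Genes transcribed downstream of ERK signalling were lower as a list in relapsed tumours, but unevenly so. The list's score was -0.66, -0.28 and -0.05 in relapsed 1, 2 and 3, against 0.27 to 0.36 in the controls. Of 19 measured members, 5 fell and none rose, or 10 fell when adjusted over the list alone, and camera gave an adjusted p of 9.61e-05, with an adjusted p of 0.463 with an estimated correlation. Etv5, Etv4 and Etv1, ETS transcription factors, fell by 1.52 ± 0.14, 1.32 ± 0.27 and 1.00 ± 0.22. Phlda1 fell by 1.03 ± 0.18, and Spry1, a feedback inhibitor of the pathway, by 0.58 ± 0.12. By mean, 18 members were lower and 1 higher. Dusp5, Spred1, Epha2 and Myc, which were not called, differed by 0.06 ± 0.39, -0.07 ± 0.20, -0.19 ± 0.30 and -0.19 ± 0.27. Dusp6, the ERK phosphatase, was 0.59 ± 0.14 lower and passed only when adjusted over the list alone, with limma adjusted p of 0.0620 over all genes and 0.0216 over the list.

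**Figure D2:**
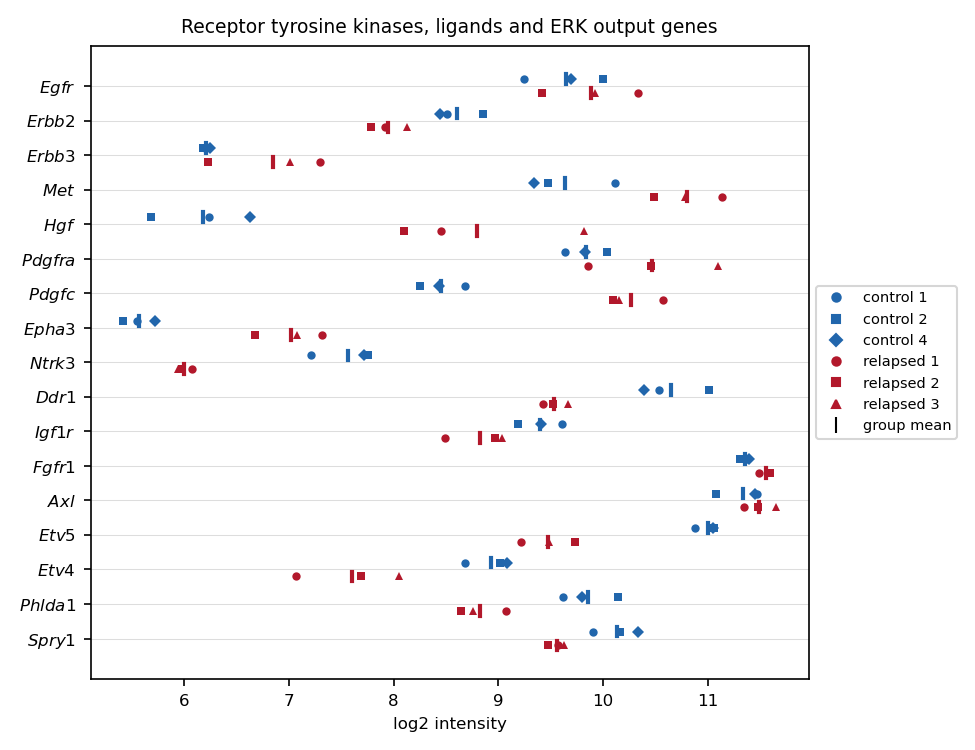
Log2 intensity (horizontal axis) of receptor tyrosine kinases, 2 of their ligands and 4 genes downstream of ERK, 1 point per array and a bar at each group's mean. Egfr values of the groups overlap, with means of 9.65 and 9.89, whereas Hgf rose from 6.19 to 8.79 and Etv5 fell from 10.99 to 9.48.

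Proneural and oligodendrocyte progenitor genes fell as a list, with an adjusted p of 3.36e-04 in camera and an adjusted p of 0.424 with an estimated correlation. Of 17 measured members, 6 fell and none rose, or 11 fell when adjusted over the list alone. Beside Olig1, Olig2 and Sox8 these were Bcan and Ncan, proteoglycans of brain extracellular matrix, at -2.65 ± 0.38 and -1.80 ± 0.29, and Nkx2-2 at -1.31 ± 0.24. Other progenitor markers of the list were not called, with differences of 0.64 ± 0.33 for Pdgfra, 0.09 ± 0.19 for Cspg4, 0.10 ± 0.16 for Gpr17 and -0.14 ± 0.08 for Sox10. Neural stem cell genes were lower as well, with 4 of 18 fallen, or 8 fallen and 1 risen when adjusted over the list alone, an adjusted p of 0.0196 in camera and an adjusted p of 0.424 with an estimated correlation. Fabp7, the fatty acid-binding protein of radial glia, fell by 2.21 ± 0.32. Msi1, an RNA-binding protein of neural progenitors, fell by 1.60 ± 0.27, Notch1 by 1.45 ± 0.10 and Sox9 by 0.66 ± 0.11. That list did not pass without control 4 (adjusted p = 0.0509) or with median centring (adjusted p = 0.0551), in a range of 0.00349 to 0.424 over its alternatives.

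No list of mature brain cell markers passed. Among 14 astrocyte markers, Gja1, a gap junction gene, rose by 2.05 ± 0.35 and Slc1a3, a glutamate transporter, fell by 1.56 ± 0.26, or 2 rose and 1 fell when adjusted over the list alone, with an adjusted p of 0.124 in camera. Of these markers 10 had a higher mean in relapsed tumours, and the list passed with quantile normalization (0.0386), median centring (0.0301) and the replicate number as a block (0.0164), in a range of 0.0164 to 0.826 over its alternatives. Among 13 neuron markers, Stmn2 rose by 2.46 ± 0.33 and Elavl4 fell by 1.54 ± 0.18, with the same counts when adjusted over the list alone and an adjusted p of 0.499 in camera. Among 9 mature oligodendrocyte markers, Cnp and Ugt8a fell by 1.31 ± 0.18 and 1.03 ± 0.16, the same 2 genes when adjusted over the list alone, with an adjusted p of 0.885 in camera.

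Mesenchymal glioma genes rose as a list, with an adjusted p of 0.00902 in camera and an adjusted p of 0.507 with an estimated correlation. Of 20 measured members, 5 rose and 1 fell, or 7 and 1 when adjusted over the list alone. S100a4 and S100a6, calcium-binding proteins, rose by 2.61 ± 0.16 and 1.56 ± 0.29, Lgals3, the galectin-3 gene, by 1.61 ± 0.23, Anxa1 by 1.18 ± 0.16 and Fn1, which encodes fibronectin, by 0.34 ± 0.06. Stat3, a transcription factor of this list, fell by 0.53 ± 0.08. By mean, 13 members were higher and 7 lower, and Cd44 and Vim, which were not called, differed by 0.13 ± 0.19 and -0.07 ± 0.05. The scores of macrophage and fibroblast markers were higher in the same tumours, by 1.24 ± 0.22 and 1.18 ± 0.27. Among 13 regulators of epithelial-mesenchymal transition and junction genes, the transcription factors Snai2 and Twist1 rose by 2.22 ± 0.42 and 2.18 ± 0.29 together with Cldn1, and Cdh2, which encodes N-cadherin, fell by 0.89 ± 0.14. This makes 3 risen and 1 fallen, or 5 and 3 when adjusted over the list alone, and the list gave an adjusted p of 0.0872 in camera.

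Markers of macrophages and microglia rose in relapsed tumours, and all 18 measured markers had a higher mean there. Of these, 11 rose and none fell, or 15 rose when adjusted over the list alone, with a median difference of 1.23. Camera gave an adjusted p of 2.49e-11, with an adjusted p of 0.424 with an estimated correlation. Mrc1, the mannose receptor, rose by 2.17 ± 0.13, Ptprc, the pan-leukocyte marker CD45, by 1.88 ± 0.36, Tyrobp, a signalling adaptor of myeloid cells, by 1.67 ± 0.20 and Itgam, which encodes CD11b, by 1.63 ± 0.18. Among 7 genes enriched in microglia, none rose and 1 fell, or 4 rose and 1 fell when adjusted over the list alone, with an adjusted p of 0.0623 in camera. The gene that fell was Sall1, at -1.04 ± 0.13, which is also transcribed in neural progenitors. Genes of MHC class II antigen presentation were higher as a list (adjusted p = 4.97e-04 in camera, adjusted p = 0.507 with an estimated correlation), with 1 of 7 risen, or 5 when adjusted over the list alone. That gene was the lysosomal protease Ctss, at 1.47 ± 0.24, and H2-Aa differed by 1.94 ± 0.43 with a limma adjusted p of 0.0541.

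Fibroblast markers rose too, with 10 of 14 measured genes risen and none fallen, the same numbers when adjusted over the list alone, and a median difference of 1.34. Camera gave an adjusted p of 2.72e-06, with an adjusted p of 0.507 with an estimated correlation. Beside Lum these included Dpt, which encodes dermatopontin, at 2.52 ± 0.47, Fap, the fibroblast activation protein, at 2.00 ± 0.40, and Dcn, which encodes decorin, at 1.85 ± 0.13. The collagen genes Col1a1, Col1a2 and Col3a1 rose by 1.13, 1.48 and 1.19. Extracellular matrix remodelling genes were higher as a list (adjusted p = 0.0196 in camera, adjusted p = 0.424 with an estimated correlation), with 2 of 19 risen, or 4 risen and 1 fallen when adjusted over the list alone. These were Plau, the urokinase gene, at 1.16 ± 0.16 and Timp2, a metalloproteinase inhibitor, at 0.65 ± 0.14. That list did not pass without control 4 (adjusted p = 0.0668) or without relapsed 1 (adjusted p = 0.0571), in a range of 0.00266 to 0.424 over its alternatives.

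Endothelial markers moved the other way. The list was lower in relapsed tumours (adjusted p = 0.0196 in camera, adjusted p = 0.597 with an estimated correlation), although only Robo4 of 14 genes fell, by 0.58 ± 0.12, the same count when adjusted over the list alone. It did not pass without control 2 (adjusted p = 0.102), without relapsed 3 (adjusted p = 0.0815) or with the replicate number as a block (adjusted p = 0.0837), in a range of 0.00257 to 0.597 over its alternatives. Among 11 pericyte and smooth muscle markers none changed, also when adjusted over the list alone, and the list gave an adjusted p of 0.529 in camera. Its smallest p-values were those of Pdgfrb at 1.20 ± 0.34 and Kcnj8 at -0.52 ± 0.19, with adjusted p of 0.0922 and 0.161 in limma.

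**Figure D3:**
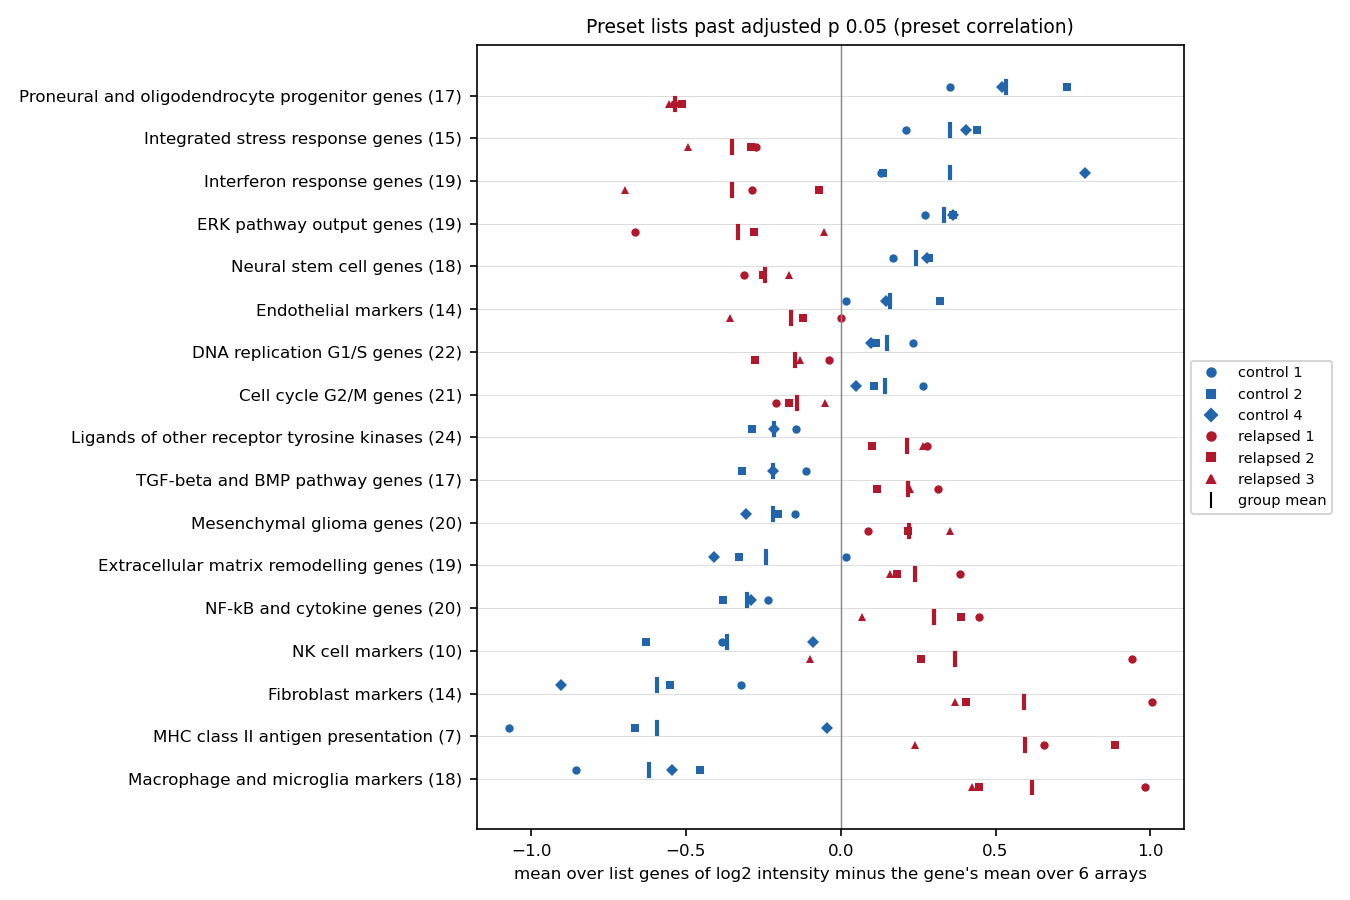
Mean over each list's genes of the log2 intensity minus the gene's mean over the 6 arrays (horizontal axis) for the 17 lists past the threshold of camera at the preset correlation, with the number of measured genes in brackets, 1 point per array and a bar at each group's mean. Macrophage and microglia markers lie at -0.86 to -0.46 in control and 0.43 to 0.98 in relapsed tumours, while the NK cell markers of the groups overlap.

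Markers of other tissues differed between single arrays of a group. Control 2 had a skeletal muscle score of 1.69 against -0.57 to 0.06 in the other arrays, and its Myh4, a myosin of fast muscle, stood at 9.60. Relapsed 1 had an adipocyte score of 2.55 against -0.75 to -0.31, with the adipokine gene Adipoq at 9.81. Relapsed 3 had a keratinocyte score of 1.34 against -0.37 to -0.17, with Krt14 at 8.58. None of the 11 muscle, 8 adipocyte and 11 keratinocyte markers was called, also when adjusted over each list alone, and the lists gave adjusted p of 0.284, 0.0678 and 0.0678 in camera. The smallest p-values belonged to Myh1 and Myh2 at -0.81 and -0.55, Lpl and Fabp4 at 1.51 and 1.73, and Perp and Dsg3 at 1.50 and 0.50. Without relapsed 1 Lpl and Fabp4 differed by 0.68 and 0.47, without relapsed 2 Fabp4 by 2.63, and without relapsed 3 Perp and Dsg3 by 0.78 and 0.042. Relapsed 1 also had the highest scores for macrophage and fibroblast markers, at 0.98 and 1.00 against 0.45 and 0.41 in relapsed 2, the next highest. With control 2 and relapsed 1 left out, a choice made after seeing the data, limma called 0 genes over all genes tested, with 5311 at an unadjusted p under 0.05. In that fit on 4 arrays, 526 of the 626 genes called at 2-fold or more still differed by at least 2-fold.

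**Figure D4:**
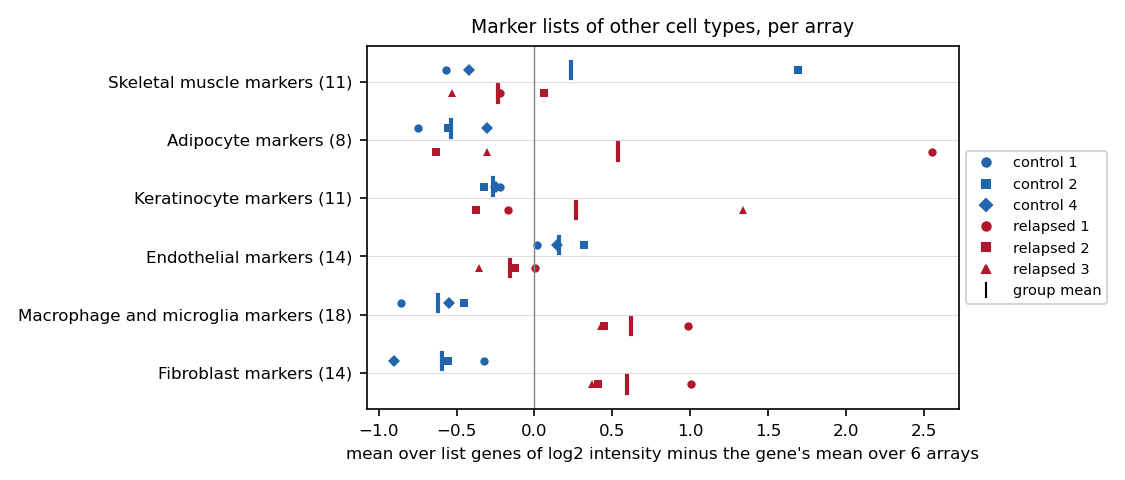
Mean over each list's genes of the log2 intensity minus the gene's mean over the 6 arrays (horizontal axis) for markers of 6 cell types, 1 point per array and a bar at each group's mean. Control 2 stands apart for muscle at 1.69, relapsed 1 for adipocytes at 2.55 and relapsed 3 for keratinocytes at 1.34.

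Of the lymphoid and granulocyte markers only 1 was called, Cd22. NK cell markers were higher as a list (adjusted p = 0.00902 in camera, adjusted p = 0.507 with an estimated correlation), but none of 10 genes was called, also when adjusted over the list alone, and the score was 0.94 in relapsed 1 against -0.10 in relapsed 3. The list did not pass in fry (adjusted p = 0.179) or in camera without control 2 and relapsed 1 (0.242), in a range of 5.78e-06 to 0.507 over its alternatives. Klrd1 and Klrk1, NK receptors, differed by 1.58 ± 0.41 and 1.09 ± 0.37, with limma adjusted p of 0.0739 and 0.133. Among 7 B cell markers, Cd22 rose by 0.51 ± 0.05, or 2 genes rose when adjusted over the list alone, with an adjusted p of 0.0678 in camera. No gene of the T cell (9), neutrophil (11) or mast cell (7) lists changed, also when adjusted over each list alone, with adjusted p of 0.233, 0.0628 and 0.233 in camera. Their smallest p-values belonged to Cd28 and Cd4 at 0.30 and -0.31, Mmp8 and Csf3r at 0.38 and 0.83, and Ms4a2 and Fcer1a at 0.38 and 0.73. Cd4 differed by -0.21 without control 4, Ms4a2 by 0.61 without relapsed 2 and 0.20 without relapsed 3, and Fcer1a by 0.40 without control 2 and 0.40 without relapsed 3. Csf3r passed without relapsed 1, with an adjusted p of 0.0435 in limma. Of 6 erythroid entries, 2 were measured, Alas2 and Epb42 at 0.32 and -0.02, and the list was not tested. Alas2 differed by -0.18 without relapsed 1 and by 0.71 without relapsed 3, and Epb42 by -0.031 to 0.014 over the fits without 1 array.

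Genes of the integrated stress response, which act in amino acid supply and redox balance, fell. Of 15 measured members, 7 fell and none rose, or 8 fell when adjusted over the list alone, and camera gave an adjusted p of 5.67e-05, with an adjusted p of 0.424 with an estimated correlation. Slc7a11, the cystine transporter, fell by 1.35 ± 0.15, Sesn2, an inhibitor of mTORC1, by 1.39 ± 0.19, Trib3 by 1.23 ± 0.18 and Chac1, a glutathione-degrading enzyme, by 1.21 ± 0.14. The level of Atf4, which encodes the central transcription factor of the response, differed by 0.04 ± 0.08.

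Cell cycle genes were lower as lists in relapsed tumours by small amounts. By mean, 4 genes of G2 and M phase and 5 of DNA replication were higher, and 17 of each list were lower. Mki67 and Pcna, which were not called, differed by 0.07 ± 0.10 and 0.15 ± 0.17. Of 21 genes of G2 and M phase 4 fell, and of 22 genes of DNA replication 4 fell, or 8 and 10 when adjusted over each list alone, and none rose in either. The adjusted p in camera was 0.00757 and 0.00902, with an adjusted p of 0.507 with an estimated correlation for each. Plk1 and Aurka, mitotic kinases, fell by 0.92 ± 0.16 and 0.71 ± 0.09, and Cdt1 and Mcm3, which license replication origins, fell by 1.07 ± 0.22 and 0.71 ± 0.08. Without control 1 the G2 and M phase list did not pass (adjusted p = 0.0606), in a range of 3.83e-04 to 0.507 over its alternatives. Kif20a and Foxm1 fell by 0.51 and 0.37, and Ccne1 and Uhrf1 fell by 0.76 and 0.48.

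Interferon response genes were lower as a list (adjusted p = 3.36e-04 in camera, adjusted p = 0.527 with an estimated correlation). All 19 measured genes had a lower mean in relapsed tumours, of which 2 fell, or 8 when adjusted over the list alone. Usp18, which limits interferon signalling, fell by 1.55 ± 0.25 and Mx2, an antiviral GTPase, by 1.30 ± 0.27. The list's score was 0.79 in control 4 against 0.13 and 0.14 in the other controls. NF-kB and cytokine genes were higher as a list (adjusted p = 1.08e-04 in camera, adjusted p = 0.424 with an estimated correlation), with 2 of 20 risen, or 4 when adjusted over the list alone. Birc3, an inhibitor of apoptosis, rose by 1.09 ± 0.22 and Vcam1, an adhesion molecule, by 0.56 ± 0.08. Genes of TGF-beta and BMP signalling were higher as well (adjusted p = 0.00388 in camera, adjusted p = 0.424 with an estimated correlation), with 3 of 17 risen, or 4 risen and 1 fallen when adjusted over the list alone. The receptors Tgfbr1 and Tgfbr2 rose by 1.12 ± 0.23 and 0.76 ± 0.15, and the ligand Tgfb1 rose by 0.74 ± 0.11. Beside both of these higher lists stand the scores of macrophage and fibroblast markers, higher by 1.24 ± 0.22 and 1.18 ± 0.27 in the same tumours.

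The remaining lists did not pass in camera. Of 12 p53 target genes 3 rose and 1 fell, or 4 and 1 when adjusted over the list alone (adjusted p = 0.166), with Eda2r at 1.17 ± 0.24, Ccng1 at 0.92 ± 0.17, Trp53inp1 at 0.78 ± 0.10 and Sesn2, which is also in the stress response list, at -1.39. Of 16 FoxO target genes Txnip rose by 1.26 ± 0.17 (adjusted p = 0.0814, from 0.0189 to 0.424 over its alternatives), of 5 tumour suppressors Rb1 rose by 0.75 ± 0.11 (adjusted p = 0.923), and of 20 Wnt pathway genes Znrf3, a ligase that removes Wnt receptors, fell by 1.24 ± 0.12 (adjusted p = 0.339), with the same counts when adjusted over each list alone. Ndufa4 rose by 1.05 ± 0.19 among 21 oxidative phosphorylation genes, the same count when adjusted over the list alone (adjusted p = 0.870). Ddit4 fell by 1.01 ± 0.20 among 20 hypoxia and glycolysis genes, a call that was lost when adjusted over the list alone (adjusted p = 0.141). Hprt rose by 0.95 ± 0.17 among 10 housekeeping genes, or 2 genes when adjusted over the list alone (adjusted p = 0.507). None of 13 BCL2 family and 8 MHC class I genes changed, also when adjusted over each list alone (adjusted p = 0.339 and 0.784), with Bcl2l11 at 0.31 ± 0.11, Bmf at 0.24 ± 0.11, Tap1 at -0.48 ± 0.38 and B2m at 0.07 ± 0.06. Tap1 differed by -0.16 without control 4, -0.72 without relapsed 2 and -0.20 without relapsed 3. Without control 2 Bmf differed by 0.13 and B2m by 0.039, and without relapsed 2 B2m differed by 0.040.

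Some lists that did not pass did so in camera when 1 array was left out. These were neutrophil markers without control 1, relapsed 1 or relapsed 3 (adjusted p = 0.0330, 0.0310 and 0.0349), B cell markers without relapsed 1 or 3 (0.0479 and 0.0170), microglia-enriched markers without control 2 or relapsed 2 (0.0454 and 0.00579) and mast cell markers without relapsed 2 (0.00527). Astrocyte markers passed without control 2 (0.0416), and the list of epithelial-mesenchymal transition without relapsed 2 (0.0264). Hypoxia and glycolysis genes passed without relapsed 2 (2.97e-04). Of the host tissue markers, adipocyte markers passed without relapsed 2 or 3 (0.00994 and 0.0213), keratinocyte markers without relapsed 1 or 2 (0.0310 and 0.00596) and skeletal muscle markers without control 1 (0.0465).

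Some of these lists also passed with another treatment of the values, mostly with higher levels in relapsed tumours. Levels were lower for hypoxia genes with all probe sets tested and for skeletal muscle with the replicate number as a block. FoxO target genes passed with quantile normalization (adjusted p = 0.0238), median centring (0.0326), the mean or median of probe sets (0.0417 and 0.0413) and fry (0.0189). With quantile normalization 7 lists were added in camera and with median centring 8, namely FoxO target genes, astrocyte, microglia-enriched, neutrophil, keratinocyte and adipocyte markers and the list of epithelial-mesenchymal transition, and with median centring B cell markers too. The replicate number as a block added astrocyte, neutrophil, B cell, adipocyte and skeletal muscle markers, p53 target genes (0.0448) and MHC class I genes (0.0113). Those results rest on control 1 and 2 and relapsed 1 and 2 only. Hypoxia and glycolysis genes passed with all probe sets tested (0.00592) and keratinocyte markers with array weights (0.0292). By ranks, microglia-enriched, neutrophil, keratinocyte and adipocyte markers passed (0.0404, 0.0463, 0.0286 and 0.0325). Without control 2, relapsed 1 and relapsed 3, a choice made after seeing the data, relapsed 2 alone stood against control 1 and 4. Its scores of T cell, B cell and skeletal muscle markers were 0.38, 0.51 and 0.06. In control 1 they were -0.18, -0.15 and -0.57, and in control 4 they were 0.12, -0.19 and -0.42.

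For 8 of the lists that did not pass, the median, the mean and the direction of camera differed in sign. The median was below 0 and the mean above 0 for EGFR family genes (-0.03 and 0.02), other receptor tyrosine kinases (-0.05 and 0.02), neuron markers (-0.06 and 0.11), oxidative phosphorylation genes (-0.08 and 0.02), housekeeping genes (-0.01 and 0.08) and BCL2 family genes (-0.02 and 0.07). For MHC class I genes the median was 0.05 and the mean -0.01, and for tumour suppressors they were -0.09 and -0.07 while camera leaned upwards.

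In all, 17 of 41 lists passed in camera at the preset correlation, 9 higher and 8 lower, and 0 passed with an estimated correlation, where 3 had an unadjusted p under 0.05 and fry called 11. The balance depends on the scaling, with 17 lists higher and 7 lower after median centring and 16 higher and 8 lower after quantile normalization. Calls lost in fry, beside that of NK cell markers, were those of G2 and M phase (0.101), DNA replication (0.0628), interferon response (0.137), MHC class II (0.0733), matrix remodelling (0.0733) and endothelial markers (0.202). Without control 2 and relapsed 1, a choice made after seeing the data, the call of matrix remodelling was lost in camera (adjusted p = 0.160), as was that of NK cell markers. Other splits of the 6 arrays into groups of 3 gave up to 18 lists, so the number of lists alone does not set the 2 groups apart.

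Whether relapsed tumours differed more among themselves than control tumours did was not settled. The median SD over genes was 0.134 in relapsed and 0.119 in control tumours, a ratio of 1.13 with an exact two-sided permutation p of 0.6, where 0.1 is the smallest that 10 splits allow. The mean absolute difference between pairs of arrays was 0.235 and 0.204, with an exact permutation p of 0.5. The other splits mix control and relapsed arrays, so their spreads also hold the difference between the groups. These permutation p-values therefore cannot decide whether the spread within the groups differs. The ratio was below 1 without relapsed 1 (0.684), whose adipocyte markers were high, and without relapsed 2 (0.979). It was 2.08 without control 2, whose muscle markers were high.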

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

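All tests of explanations in this part were chosen after the results were seen, while the counts over other splits of the arrays were planned.

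Probe sets outside the gene comparison also differed between the groups by limma with Benjamini-Hochberg adjustment over all probe sets. Among 1621 probe sets with several gene symbols, 75 were higher and 7 lower in relapsed tumours. Over all 35556 probe sets, 871 were higher and 860 lower. Some of the 75 carry identical values for the same genes, so they are not 75 separate findings. Among 12146 probe sets not listed with a gene, 189 were higher and 114 lower.

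Of the 10 splits of the 6 arrays into groups of 3, 1 gave as many genes as the real one, namely the real one itself, with 1826 called against 0 as the highest of the others. For changes of at least 2-fold, 1 split gave as many, with 626 against 0. For gene lists, 2 splits gave as many, with 17 lists in the real split and 18 in the highest of the others. A set of 10 splits is too few for a share under 0.05.

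Macrophage and fibroblast markers were higher in relapsed tumours as lists in camera, with adjusted p of 0.424 and 0.507 with an estimated correlation, while endothelial markers were not. An even rise of all host cells would carry endothelial markers along, but the macrophage score minus the endothelial score rose by 1.56 ± 0.13 (SE), which argues against that as the whole cause. Carry-over of fat, skin or muscle at dissection stays open. For all of these tissues together, 0 of the 3 relapsed arrays had scores within controls 1 and 4. The macrophage and fibroblast scores of relapsed 2 lay 0.903 and 0.726 above the highest control. Its muscle score was 0.06, against -0.57 and -0.42 in controls 1 and 4. Its adipocyte score of -0.63 lay between those of controls 1 and 4, and its keratinocyte score of -0.37 lay below both. Control 2, with a muscle score of 1.69, had macrophage and fibroblast scores of -0.46 and -0.55. These values rest on single arrays and do not settle the question. A larger share of female host cells beside male tumour cells stays open too: Xist rose by 1.60 ± 0.28 with an adjusted p of 0.0323 in limma, while the mean of the Y-linked genes Uty, Eif2s3y and Kdm5d differed by 0.102 ± 0.358, and the sex of cells and hosts is not given in the labels. A larger number of macrophages and fibroblasts, or a higher output of these genes per cell or by tumour cells, may underlie the pattern and was not tested.

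Proneural and oligodendrocyte progenitor genes were lower in relapsed tumours as a list in camera, with an adjusted p of 0.424 with an estimated correlation. Dilution of tumour cells by host cells would lower other genes of the neural lineage by the same factor, but the proneural score minus the astrocyte score fell by 1.43 ± 0.26 (SE). Without the astrocyte markers Gja1, Glul, Sparcl1, Clu, Apoe and S100b, which host cells also make, it fell by 1.13 ± 0.36. The remaining markers went both ways, with differences of -1.56 ± 0.26 for Slc1a3 and -0.80 ± 0.40 for Aldoc, which dilution predicts, and of 0.64 ± 0.48 for Gfap and 1.04 ± 0.37 for Aqp4, which it does not. The scores argue against dilution as the whole cause but not against a part of it, and a shift of tumour cells away from the progenitor state is a hypothesis that the design allows and these arrays do not separate from the outgrowth of other tumour cells.

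ERK output genes were lower in relapsed tumours as a list in camera, with an adjusted p of 0.463 with an estimated correlation. Dilution of tumour cells could lower them too, and the ERK output score minus the neural stem cell score differed by -0.178 ± 0.137 (SE), within 2 SE of 0. The neural stem cell score was itself lower, by 0.488 ± 0.057. The astrocyte score used for proneural genes was not lower, at 0.355 ± 0.330, against -0.666 ± 0.181 for ERK output. Without markers that host cells also make, the astrocyte score differed by 0.057 ± 0.430. The comparison thus depends on the reference list. Less ERK signalling per tumour cell and a smaller share of tumour cells therefore cannot be told apart for this list.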

How the results depend on the processing

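Leaving out 2 or 3 arrays with high marker levels of other tissues was chosen after seeing the data, and the other alternatives were planned. The cause of these shifts was not tested. Against 1826 genes, 626 of them at 2-fold or more, limma called 875 and 321 with a floor on low values and 105 and 47 without variance moderation. With the replicate number as a block, which need not pair tumours, it called 0 and 0 genes, with 2199 at an unadjusted p under 0.05. Leaving out 1 array at a time gave 264 to 975 genes, 157 to 376 at 2-fold and 15 to 23 lists. Against 17 lists, 0 passed with an estimated correlation and 11 with fry. Without control 2 and relapsed 1, limma called 0 and 0 genes (5311 unadjusted) and 15 lists, while 526 of the 626 genes still differed by at least 2-fold. Without relapsed 3 as well, relapsed 2 was the only relapsed array, and 488 of the 626 genes still differed by at least 2-fold. All other totals, those of that last fit aside, lay within 1.5 times. By direction, 17, 16 and 15 lists were higher with median centring, quantile normalization and the block, against 9, and 14 without relapsed 2. With median centring 1687 genes fell, against 1091.

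The values below turned direction, and none of these results was called. With the dimmer 50% of genes left out, adjusted p were 0.459 for neuron markers and 0.788 for oxidative phosphorylation, and the spread ratio was 0.983. Quantile normalization gave 0.860 for oxidative phosphorylation, and median centring 0.913 for the EGFR family and a difference of -3.68e-04 for B2m. Testing all probe sets gave 0.518 for other receptor tyrosine kinases and 0.865 for tumour suppressors. Array weights gave 0.967 for both receptor lists, 0.887 for oxidative phosphorylation and a difference of 0.00386 for Epb42. The replicate block gave 0.676 for oligodendrocyte markers, 0.785 for tumour suppressors and a difference of 0.12 for Tap1. Fry gave 0.490 for other receptor tyrosine kinases, and ranks 0.947 for oligodendrocyte markers and 0.869 for tumour suppressors.

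Without control 2 and relapsed 1, adjusted p were 0.974 for EGFR family and pericyte lists, 0.662 for other receptor tyrosine kinases, 0.658 for oxidative phosphorylation, 0.925 for tumour suppressors and 0.331 for skeletal muscle, and differences were -0.22 for Alas2 and 0.021 for Epb42. Without relapsed 3 as well, adjusted p were 0.987 for EGFR family and oligodendrocyte lists, 0.495 for other receptor tyrosine kinases, 0.317 for hypoxia, 0.312 for tumour suppressors, 0.416 for mast cells, 0.543 for pericytes, 0.290 for keratinocytes and 0.465 for adipocytes. Skeletal muscle, at 0.0340, was the only one past the threshold. Differences there were -0.054 for Egfr, -0.064 for Ms4a2, -0.16 for Fcer1a, -0.037 for Perp, -0.17 for Fabp4 and 0.021 for Epb42.

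Some results turned direction when 1 array was left out, and their ranges over the 6 such fits follow. Adjusted p ran from 0.646 to 0.952 for the EGFR family, 0.555 to 0.974 for other receptor tyrosine kinases, 0.414 to 0.855 for oligodendrocyte markers, 0.158 to 0.997 for MHC class I, 0.476 to 0.982 for oxidative phosphorylation, 0.701 to 0.940 for tumour suppressors, 0.273 to 0.820 for pericytes, 0.00596 to 0.729 for keratinocytes and 0.0465 to 0.487 for skeletal muscle. The low ends for keratinocytes and muscle kept the direction. Differences ran from -0.18 to 0.71 for Alas2 and from -0.031 to 0.014 for Epb42, and the spread ratio from 0.684 to 2.08. The spread ratio in these fits compares groups of unequal size, so its turns cannot be read as a change in spread.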

Other observations

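Probe sets that match several related genes are left out of the gene comparison. The largest rises among them, singled out after their values were seen, were 2.18 ± 0.36 (SE) for a probe set shared by the Sirpb1 genes, receptors of myeloid cells, and 2.03 ± 0.22 for a probe set shared by the Bcl2a1 genes, anti-apoptotic members of the BCL2 family that are strong in leukocytes, with adjusted p of 0.0391 and 0.0208 in limma. Several probe sets shared by clustered zinc finger genes were higher in relapsed tumours as well, the largest at 1.48 ± 0.16 with an adjusted p of 0.0208 in limma. So were several that include ribosomal protein genes. Some of the zinc finger probe sets carry identical values. These groups were also picked out after their values were seen, and no gene family was tested as a set. These probe sets cannot assign the signal to 1 member of a family.

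Nefl, the neurofilament light chain, stood at 12.51 in relapsed 3 against 6.08 to 8.05 in the other 5 arrays, the array that also had high keratinocyte markers. Tnfrsf10b, a death receptor, was 8.72 ± 0.28 (SD) in control and 7.53 ± 1.12 in relapsed tumours, and Btc, an EGFR ligand, was 5.83 ± 0.21 in control and 7.25 ± 1.44 in relapsed tumours, so that relapsed tumours differed among themselves for both. Neither passed the test between groups, with adjusted p of 0.258 and 0.280 in limma. These 3 genes were chosen after their values were seen.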
